A study of Mus musculus with 4 samples.

How the data were processed

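Total RNA of 4 mouse yolk sac samples from embryonic day 9.5, of the strain given as C57BL/6, was measured on Illumina bead arrays, with 2 samples labelled ETV2 CKO and 2 labelled control. Per the labels' protocols, RNA was extracted with Trizol, cleaned on a column with DNase treatment, and turned into biotin-labelled cRNA. The authors deposited a table of non-normalized probe signals, which per the file headers holds 1 intensity column for each array on a linear scale, with no background subtracted as judged from the values. Beside each intensity the deposited table holds a detection p-value, the chance of such a signal from negative control beads. Each detection column was tied to its array by the column to its left, since its values fall steadily as that signal rises. The software lumi 2.15.1 is listed in the submitters' processing notes, with no role given, and other steps are not given in the sources used here.

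The authors' processed value table holds intensity values on a linear scale with a median of 201.4 on each array. Its columns had been brought to the same distribution (sorted values differ by at most 7.79 of a maximum of 23810), and each column ranks the probes exactly as the raw signal does. What was done beside that quantile step stays unknown, so this table served as an alternative only. That includes the step that lifted the lowest values to 179.2, from raw minima between 83.9 and 92.7. No column of per-sample values was left out.

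The array has 45281 probes, of which 34885 carry 1 gene symbol in the platform annotation, 18 carry several and 10378 are unnamed here. Looking the entrez identifiers up in a RefSeq gene table of assembly GRCm38.p6 changed 0 symbols. That table was used for names and for the order of neighbouring genes, and no coordinates are given, because no genome build of the array is named in the sources used here.

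Signals were background-corrected and normalized with the neqc function of limma 3.58.1 in R 4.3.3, which infers the background from the detection p-values, adds an offset of 16, applies quantile normalization and takes log2. Probes with a detection p under 0.05 on at least 2 of the 4 arrays were kept, 18817 in all, of which 16301 were named. For a gene with several such probes the one with the highest mean over all 4 arrays was used. The 2516 unnamed probes were tested apart, and 230 of them were lower and 220 higher on the CKO-labelled arrays. Fold changes were tested with lmFit and eBayes of limma on group alone, 2-sided, with Benjamini-Hochberg adjustment over 10603 genes and a threshold of 0.05. The moderated test had 6.54 degrees of freedom in all and a median standard error of 0.105 on the log2 scale. An exact permutation test of 2 against 2 samples cannot give a 2-sided p below 0.333, so no single value can pass 0.05 on its own ranks, and the p-values rest on the spread that limma shares across genes.

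Where a gene was not above background on any array of a group, its fold is given as a bound, "at least N-fold". It sets the bright group's mean against the mean over the dim group's arrays of the lowest normalized signal above background or the probe's own, whichever was higher. This applied to 347 genes. Differences are otherwise log2 values of CKO-labelled minus control arrays with the standard error of the fit. The offset and the background of a bead array pull the changes of dim genes towards 0.

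The 23 gene lists, the tests, the filters, the alternatives and the rule for named genes were fixed before the data were examined. The rule took Etv2 and Kdr, the 12 largest decreases and the 12 largest increases among named genes past the threshold whose groups did not overlap, and up to 4 members of largest change past the threshold from each list. Further genes are named as counts of 5 or fewer, as other members of a list or as members that did not pass, and these were chosen after their values were seen. Lists were tested with limma's camera at its preset correlation of 0.01, adjusted over 21 lists. A minimum of 3 tested members was set after the files had been seen, and it left out the paraxial mesoderm list, with 0 tested genes, and the neural and ectoderm list, with 1, in which Nes rose by 0.73. Camera called 7 lists, 4 up and 3 down. With the correlation estimated from the residuals it called 0 of 21, 3 of them having an unadjusted p under 0.05 (lowest 0.0241). That form of camera also rests on the few residual degrees of freedom of 4 arrays. A call lost in it can therefore reflect the number of arrays. The estimated correlation was below the preset 0.01 for heme synthesis (0.0072), mesenchyme (0.0073), hematopoietic progenitor (-0.045) and angiogenic ligand genes (-0.066). The calls of those lists were therefore not lost through a larger correlation. limma's fry, which asks whether a list moves on balance one way without comparing it with other genes, called 14. The fry test for change in either direction called 21.

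The main test was checked on simulated data with 10603 genes and 200 of them changed. It recovered 22.4% of the genes changed by 0.5 on the log2 scale, 89.6% of those changed by 1 and 100% of those changed by 2, with 7 false calls among 148. Of 200 simulated unchanged lists 0 were called, and 20 of 20 lists shifted by 0.5 were. The simulated noise was independent between genes and the lists were drawn at random, so this does not check false calls among correlated genes. In the data the estimated correlation reached 0.287 for hemangiogenic factors and 0.232 for cardiac genes. With 2671 genes called in the data against 200 changed in the simulation, the recovered shares need not carry over. Small changes could still be missed at this number of arrays.

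For arrays, the signal over background sets what can be seen. The raw median intensity was 117.5 and 125.1 on the CKO-labelled arrays and 108.8 and 114.5 on the control arrays, and 41.5%, 41.1%, 39.9% and 39.6% of probes were detected in the same order. Normalized values correlated across genes at 0.996 between the arrays of either group and at 0.984 between groups, although genes are not independent replicates. Alternatives changed the background correction, normalization, filter, variance model, probe choice, threshold, source of values, replicate block, set test and list overlap, and left out each array in turn. With 1 array left out, a group holds a single array and the spread comes from the 2 arrays of the other group, shared across genes by limma, so a call lost in such a fit can reflect the smaller number of arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.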

Results

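Total RNA from mouse yolk sacs at embryonic day 9.5 was profiled on Illumina bead arrays, on which each gene is read as the fluorescence of beads that carry a short probe. The yolk sac is an extraembryonic membrane in which the earliest blood cells and vessels form beside an endoderm layer and a mesothelium. There were 2 groups of 2 arrays, labelled ETV2 CKO and control, which the deposited signal columns name Mut and WT. Per the labels, the first group carried a loxP-Cre deletion of Etv2. It was made with a Cre recombinase named for Flk1, an older name of the vascular endothelial growth factor receptor gene Kdr. The group names do not say whether control samples carried the Cre or the loxP sites. An effect of either is therefore not separated from that of the deletion in any value here. Etv2 encodes an ETS-family transcription factor needed for the formation of endothelial and blood cells. The comparison asks which yolk sac transcripts differ between samples with these 2 labels. Between 17934 and 18798 of 45281 probes were above background on each array, and 10603 named genes were tested. The number of arrays, 2 a group, limits the precision of every value. The labels do not say that the arrays came from separate embryos or litters, so p-values measure only the spread between these samples, which may be technical.

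The targeted gene did not separate the groups in the direction of the labels. Its probe was above background on all 4 arrays, with raw intensities of 206 and 227 on the CKO-labelled arrays against 157 and 177 on the control arrays. The normalized log2 difference was 0.46 ± 0.10 (SE, n = 2 a group), higher on the CKO-labelled arrays, with a limma adjusted p of 0.0199. Over 15 alternatives it ranged from 0.13 to 0.56, and 4 of them ended the call, namely the authors' values and leaving out either CKO replicate or control replicate 1 (limma adjusted p between 0.00568 and 0.0816 over all 15). Whether this Etv2 probe lies inside the deleted part of the gene is not known here, and a probe outside it checks nothing, so the group names below rest on the labels alone. Both Kdr probes were below the detection threshold on each of the 4 arrays, and Kdr was therefore not tested.

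On the CKO-labelled arrays 20 of 29 erythroid genes fell, while 11 of 13 parietal endoderm, 10 of 14 cardiac muscle and 15 of 25 mesenchyme genes rose and endothelial genes went both ways. limma's camera called these 4 lists, and none of the 4 calls held with an estimated correlation, at adjusted p-values of 0.289, 0.289, 0.337 and 0.289 in that order. That form of camera rests on few residual degrees of freedom, so a call lost in it does not show that a list is unchanged. The arterial connexin gene Gja5 fell by 2.67 ± 0.11 on the log2 scale (6.34-fold, SE, n = 2 a group), and Gja4, which encodes the other connexin of arterial endothelium, fell by 2.18 ± 0.16, and the transferrin receptor gene Tfrc, through which red cell precursors take up iron, by 1.71 ± 0.09. At the other end, Vtn, which encodes the adhesive plasma protein vitronectin, rose by 3.16 ± 0.11 (8.93-fold). The basement membrane laminin gene Lama1 rose by 1.55 ± 0.11, and the stem cell factor receptor gene Kit rose by 1.63 ± 0.09.

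Of the 10603 genes, 1144 were lower and 1527 higher on the CKO-labelled arrays at a limma adjusted p under 0.05, and 77 of the former and 138 of the latter differed at least 2-fold. The groups did not overlap for 65.4% of genes, where chance gives 33.3%. The split between directions moved with the scaling, from 57.2% of calls higher to 70.3% under median scaling (649 lower and 1535 higher). Leaving out 1 array lowered the counts to 545 lower and 751 higher without CKO replicate 1, 549 and 797 without CKO replicate 2, 648 and 1002 without control replicate 1, and 671 and 1013 without control replicate 2. In each of these fits 1 group has a single array, assumed to vary like the 2 arrays of the other group. Xist was higher on the CKO-labelled arrays by 1.05 ± 0.10 and the Y-linked gene Eif2s3y fell by 0.73 ± 0.11, both above background on all 4 arrays, and since the labels give neither sex nor pooling, sex make-up is not separated from the group in any value here.

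**Figure D1:**
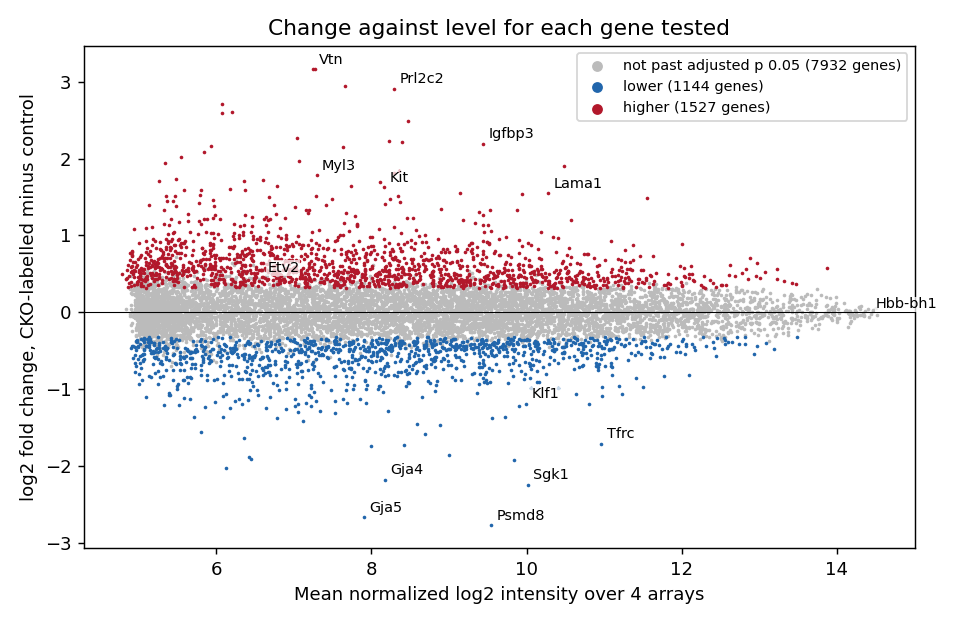
The log2 fold change between CKO-labelled and control arrays (vertical axis, log2 units) is plotted against the mean normalized log2 intensity over 4 arrays (horizontal axis) for each of the 10603 genes tested, with 1144 lower genes in blue, 1527 higher genes in red and the rest in grey. Gja5 at -2.67 and Vtn at 3.16 lie near the extremes, and the embryonic globin gene Hbb-bh1 lies at the bright end at -0.02.

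The 12 largest decreases ran from Psmd8, a proteasome subunit gene, at -2.77 to Tfrc at -1.71. Between them stood Gja5, Sgk1 at -2.24, Gja4, Cfap57 at -2.03, Fbp2 at -1.92, Clasrp at -1.90, Slc7a3 at -1.88, Slc39a8 at -1.86, Dusp4 at -1.74 and Fcgr3 at -1.73. Sgk1 encodes a serum- and glucocorticoid-induced kinase, Slc7a3 a transporter of cationic amino acids, and Fcgr3 an immunoglobulin receptor of myeloid cells. The Slc7a3 value came from the brighter of 2 probes, the other of which stood at 0.07. Cfap57 was above background on 1 of the 2 CKO-labelled arrays and on both control arrays. The limma adjusted p of these genes lay between 0.000193 for Psmd8 and 0.00167 for Cfap57.

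The 12 largest increases began with Prl2c4 at 3.17, followed by Vtn, Prl2c3 at 2.94 and Prl2c2 at 2.91. The Prl2c genes encode proliferins, prolactin-family hormones of trophoblast giant cells, and they are near-identical copies, so which of them the probes measured is uncertain. For 3 of the genes the control arrays were below background and only a bound was measured, at least 5.35-fold for Fst, at least 5.06-fold for Klk6 and at least 4.86-fold for Slc6a2. Fst encodes follistatin, an activin antagonist, and Slc6a2 the noradrenaline transporter. The others were Hs3st1 at 2.49, Slc5a4b at 2.26, the tight junction gene Cldn1 at 2.23, Fxyd3 at 2.22 and Igfbp3, a binding protein gene of insulin-like growth factors, at 2.19. Klk6 and Fxyd3, and Psmd8 among the decreases, lie within 50 tested genes of Etv2.

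Among 34 tested genes of the endothelial list, 6 fell, 6 rose and 22 did not pass the test, or 6 and 8 of them adjusted over the list alone. The median log2 change was 0.01 (SD over genes 0.447), with a limma camera adjusted p of 0.948, and 0.972 with an estimated correlation. The SOX factor genes Sox7 and Sox17 rose by 1.23 ± 0.12 and 0.79 ± 0.09, the guidance receptor gene Robo4 by 0.80 ± 0.10 and the kinase gene Prkch by 0.76 ± 0.10, and Adgrl4 and the endothelial cadherin gene Cdh5 also rose, at 0.65 and 0.43. A dimmer probe of Sox7 stood at -0.00. RNA of yolk sac tissue does not show which cells made a transcript, so changes in this list are not tied to endothelium. The genes that fell were Plvap at -0.70, Tie1 at -0.62, Emcn at -0.58, Vwf at -0.51, Flt1 at -0.45 and Arhgef15 at -0.39. Pecam1 at 0.18 and Tek at -0.09 did not pass the test.

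Of 11 arterial and Notch genes, 3 fell and 2 rose, and adjusted over the list alone these counts were again 3 and 2. Gja5, Gja4 and the netrin receptor gene Unc5b, at -0.40, were the ones that fell. The chemokine receptor gene Cxcr4 rose at least 2.64-fold, being below background on the control arrays, and Nrp1 rose by 0.57 ± 0.11, although its dimmest probe stood at -0.09. The Notch target gene Hey1 stood at -0.00 and did not pass. The list as a whole had a median of -0.00, a mean of -0.27 and a camera adjusted p of 0.543, or 0.762 with an estimated correlation (limma).

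In the venous and lymphatic list, 2 of 11 genes fell and 3 rose, with the same counts adjusted over the list alone. The scavenger receptor gene Stab2 fell by 0.63 ± 0.13 and the sialomucin gene Emcn by 0.58 ± 0.13, while the lymphatic marker genes Pdpn and Lyve1 rose by 0.47 and 0.32. Nrp2 was at 0.45 by its brightest probe and at -0.11 by another. The median of 0.03 and the mean of -0.02 differed in sign, the test pointed down, and its limma camera adjusted p was 0.948, or 0.972 with an estimated correlation.

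Transcription factors of the blood and vessel lineage split in the same manner, with 6 of 20 lower, 4 higher and 10 not past the test, or 6 and 5 adjusted over the list alone. The flow-responsive factor gene Klf2 fell by 1.17 ± 0.15 and Tal1, a regulator of blood cell formation, by 0.70 ± 0.12. Lyl1 at -0.56, Gfi1b at -0.52, Cbfa2t3 at -0.45 and Lmo2 at -0.41 also fell. Sox7, Sox17, Nfatc1 at 0.56 and Meis1 at 0.49 rose. The median was -0.06, with a limma camera adjusted p of 0.447 and 0.842 with an estimated correlation. The list shares 5 tested genes with the endothelial list, Sox7 and Sox17 among them. With each gene counted only in its first list, the median over 15 genes was -0.18 (limma camera adjusted p = 0.0989).

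Among the 21 lists the erythroid one had the largest share of lower genes. Of its 29 tested genes, 20 fell and 9 did not pass, and 22 fell adjusted over the list alone. The median was -0.54 (-0.32 on the authors' values) with a limma camera adjusted p of 2.56e-11. With an estimated correlation that call was lost, at an adjusted p of 0.289. Beside Tfrc, the erythroid transcription factor genes Klf1 and Gata1 fell by 1.19 ± 0.10 and 1.16 ± 0.11, and the Rh complex gene Rhag by 1.17 ± 0.11. The globin genes Hba-x at -0.05, Hba-a1 at -0.03, Hbb-bh1 at -0.02 and Hbb-y at 0.02 did not pass the test, and their signals lay between 85.5% and 100% of the brightest probe on each array. Hbb-b2, an adult-type globin gene, fell by 0.74 ± 0.11.

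Heme synthesis genes went the same way, with 6 of 12 lower and 6 not past the test, or 8 lower adjusted over the list alone. The mitochondrial iron importer gene Slc25a37 fell by 0.98 ± 0.10, the ferrochelatase gene Fech by 0.76 ± 0.10 (the dimmest of its 4 probes stood at 0.30), Uros by 0.57 and the first-step enzyme gene Alas2 by 0.51. The median was -0.35, with a limma camera adjusted p of 5.02e-05 and an adjusted p of 0.289 with an estimated correlation. The list shares 2 tested genes with the erythroid list.

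Of 23 hematopoietic progenitor genes, 6 fell and 1 rose, and 7 fell and 1 rose adjusted over the list alone. The lymphoid and stem cell factor gene Ikzf1 fell by 0.78 ± 0.11, beside Tal1, Lyl1, Gfi1b, Cbfa2t3 and Arhgdib, whereas Kit rose. Runx1 stood at -0.15 ± 0.21 and Myb at -0.01 ± 0.11, and neither passed the test. The median of -0.15 was -0.093 without background correction, -0.092 under median scaling, -0.056 on the authors' values and -0.27 without CKO replicate 2. It had a limma camera adjusted p of 0.024. The call was lost with an estimated correlation (adjusted p = 0.337), without control replicate 2 (-0.12, limma adjusted p = 0.0527), and with each gene counted only in its first list (-0.074, limma adjusted p = 0.415).

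The lists of the other blood lineages were not called by camera, although limma's fry called both, myeloid genes down (adjusted p = 0.0125) and megakaryocyte genes up (adjusted p = 0.0137). In the macrophage and myeloid list, 4 of 14 fell and 3 rose, or 5 and 3 adjusted over the list alone. Fcgr3 fell, as did the granule protease and peroxidase genes Prtn3 at -1.07 and Mpo at -0.64 and the actin-bundling gene Lcp1 at -0.80, while the macrophage growth factor receptor gene Csf1r rose by 1.13 ± 0.14. The list's median was -0.05 (limma camera adjusted p = 0.285, and 0.483 with an estimated correlation). Of 16 megakaryocyte genes, Vwf fell, F2rl2 rose by 0.57 and Pf4 by 0.39, and 13 did not pass, with the same counts of 1 and 2 adjusted over the list alone. The megakaryocyte median was 0.12, or 0.050 without background correction, 0.19 under median scaling and 0.024 on the authors' values (limma camera adjusted p = 0.336, and 0.483 with an estimated correlation).

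**Figure D2:**
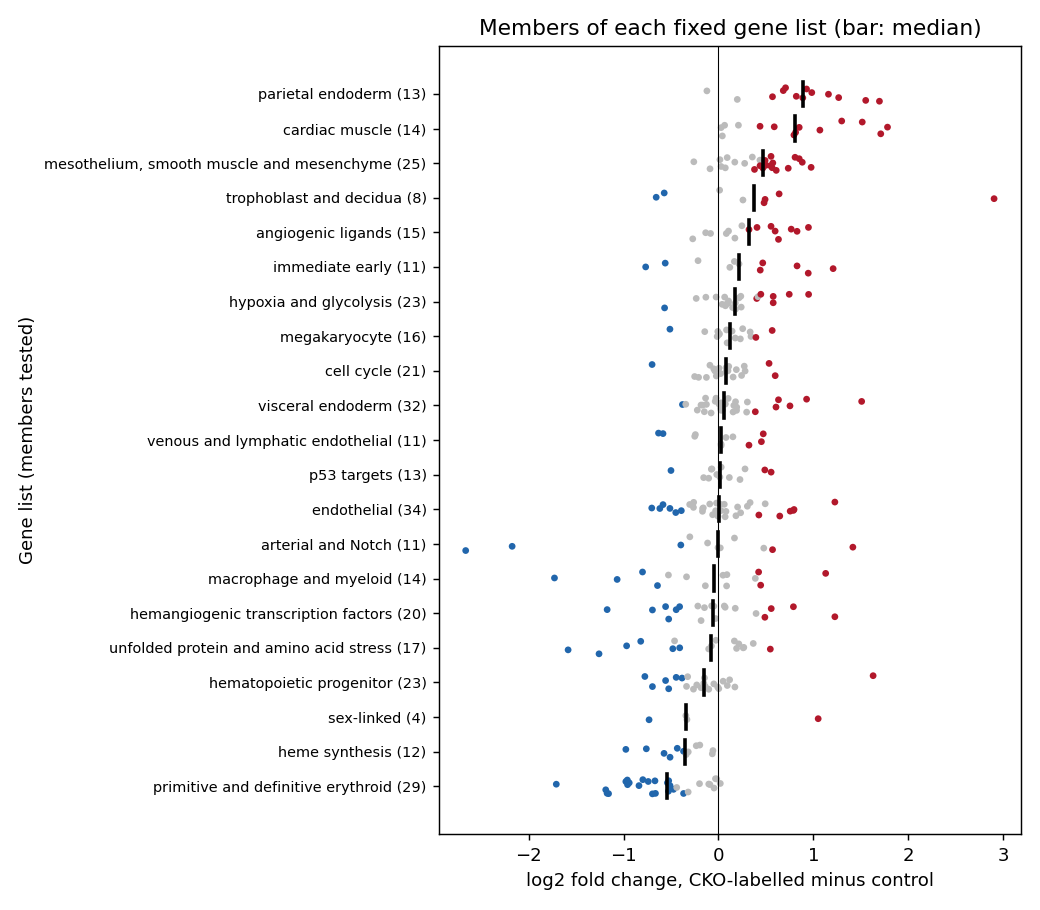
The log2 fold change of each tested member (points, horizontal axis, CKO-labelled minus control) is shown for 21 gene lists (vertical axis, number of members tested in parentheses), with genes past the test in blue (lower) or red (higher), others in grey and the list median as a black bar. The erythroid median lies at -0.54 and the parietal endoderm median at 0.89, while the endothelial median lies at 0.01 with members on both sides.

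The parietal endoderm list had the largest share of higher genes among the 21 lists. Of 13 tested genes, 11 rose and 2 did not pass, with 11 also adjusted over the list alone. Plat, the tissue plasminogen activator gene, rose by 1.70 ± 0.09, Lama1 by 1.55, the nidogen gene Nid1 by 1.27 ± 0.09 and the parathyroid hormone receptor gene Pth1r by 1.16 ± 0.13. The median was 0.89, with a limma camera adjusted p of 2.06e-07 and an adjusted p of 0.289 with an estimated correlation. All 13 genes were above background on both control arrays. Prl2c2, Prl2c3 and Prl2c4 of giant cells, which adjoin the parietal endoderm, were higher on the CKO-labelled arrays by 2.91 to 3.17. A further Prl2c2 probe was above background on the CKO-labelled arrays only, and Prl2c1 and Prl2c5 were not above background on any array.

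The mesothelium, smooth muscle and mesenchyme list rose in 15 of 25 genes, with 10 not past the test, or 17 higher and 1 lower adjusted over the list alone. The collagen gene Col3a1 rose by 0.98 ± 0.12, the growth factor receptor gene Pdgfra by 0.88 ± 0.09, Hand2 by 0.85 ± 0.15 and the proteoglycan gene Dcn by 0.81 ± 0.12. The smooth muscle genes Acta2 at 0.02 and Tagln at 0.03 did not pass the test. The median was 0.47 (0.44 with dim genes at their bounds, 0.27 without background correction and 0.17 on the authors' values), with a limma camera adjusted p of 4.71e-05 and an adjusted p of 0.289 with an estimated correlation.

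Of 14 cardiac muscle genes, 10 rose and 4 did not pass, with 10 adjusted over the list alone. Myl3, a myosin light chain gene, rose by 1.78 ± 0.11 and the troponin gene Tnnc1 by 1.30 ± 0.09, and the myosin light chain genes Myl2 and Myl7 each rose at least 2.03-fold from control arrays below background. The median was 0.80 (0.70 with dim genes at their bounds), but 0.36 over 22 genes with no filter on dim probes, 0.31 without background correction and 0.16 on the authors' values. The limma camera adjusted p was 7.67e-06, and the call was lost with an estimated correlation, at an adjusted p of 0.337. The cardiac list shares 2 tested genes with the mesenchyme list.

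Visceral endoderm genes were for the most part not past the test, with 1 of 32 lower and 6 higher, and the same counts adjusted over the list alone. The forkhead factor gene Foxa1 rose by 1.51 ± 0.10, Gata6 by 0.75 ± 0.09 and the signal gene Ihh by 0.63 ± 0.10, and the hemopexin gene Hpx rose at least 1.39-fold. Apoe fell by 0.38, while Afp at 0.15, Ttr at -0.03 and Apoa1 at 0.01 did not pass. The mean log2 levels of Ttr and Apoa1, 14.26 and 14.25, lay close to those of the 4 globin genes near the top of the array, 14.35 to 14.52. The median was 0.05 (limma camera adjusted p = 0.336, and 0.483 with an estimated correlation). Of 8 trophoblast and decidua genes, 4 rose and 2 fell, or 5 and 2 adjusted over the list alone. Beside Prl2c2, the prolactin-family gene Prl8a2 rose at least 1.39-fold and Prl4a1 fell by 0.66 ± 0.12, and the deiodinase gene Dio3 fell by 0.57 ± 0.12. The trophoblast median was 0.37 (limma camera adjusted p = 0.242, and 0.483 with an estimated correlation), and it was 0.22 without background correction, 0.13 on the authors' values and, over 20 genes with no filter on dim probes, -0.0072.

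Angiogenic ligand genes rose in 8 of 15 cases, with 7 not past the test and 8 also adjusted over the list alone. The matricellular genes Ccn2 and Ccn1 rose by 0.95 ± 0.09 and 0.83 ± 0.13, the chemokine gene Cxcl12 by 0.77 ± 0.09 (the lowest of its 3 probes above background stood at -0.11), and Ihh as above. Vegfa stood at 0.11 ± 0.11 and did not pass. The median was 0.32 (0.25 with dim genes at their bounds, 0.21 without background correction, 0.17 with no filter on dim probes and 0.12 on the authors' values), with a limma camera adjusted p of 0.00842. The call was lost with an estimated correlation (adjusted p = 0.337) and with each gene counted only in its first list (limma adjusted p = 0.0582).

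**Figure D3:**
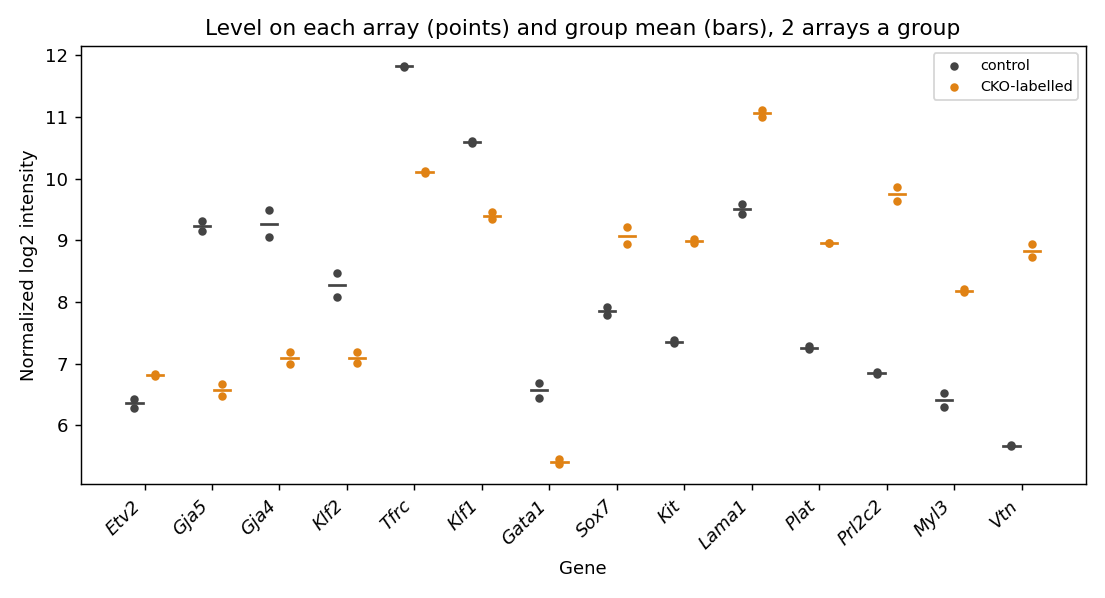
The normalized log2 intensity (vertical axis) of 14 genes (horizontal axis) is shown for each array as a point, with the mean of the 2 arrays of a group as a bar, control in grey and CKO-labelled in orange. The groups do not overlap for any of these genes, and Etv2 is among those with higher points on the CKO-labelled arrays.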

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

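The alternatives below were all planned. Signal over background limits the dim genes, of which 347 have only a bound in 1 group. A slide block was not run because the files name no slide. Counts of lower genes moved from 1144 to 649 under median scaling, 1936 with every probe tested, 77 at 2-fold or more, and 545 to 671 with 1 array left out. Counts of higher genes moved from 1527 to 138 at 2-fold or more and to between 751 and 1013 with 1 array left out. Fewer samples or a stricter threshold account for these last falls. The 1936 with every probe tested is a count of probes out of 18817, unnamed ones included. It is therefore not comparable with the 1144 of 10603 genes. The cause of the fall under median scaling was not tested. Median scaling shifted the median of all genes to 0.07, from 0.02. The authors' processed values gave 1400 lower and 1679 higher genes, with 2059 of 2671 calls kept. Of the calls tested again, 1 changed sign under the stricter detection filter and 11 with a gene's probes averaged.

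The arrays share replicate numbers, but nothing in the labels says that a number marks a litter or day, and the deviations of same-numbered arrays correlated at only 0.066 across genes. With a replicate block there were 1164 lower and 1561 higher genes, 2519 of the 2671 calls kept, and the hypoxia and glycolysis list passed at 0.18 (limma adjusted p = 0.0446). The block changed no other list call and no named gene's call.

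Of 273 list values under alternatives, 252 stayed on their side of the threshold, 10 lost and 11 gained a call, and 0 called ones reversed. Called medians that shrank by over 1.5 times without background correction, without the filter, under median scaling or on the authors' values (cardiac, mesenchyme, angiogenic, progenitor and erythroid genes) are given beside those lists. The medians of the 14 lists not called all moved by over 1.5 times under at least 1 alternative, and 7 changed sign. With an estimated correlation, which is a change of the test and leaves the medians as they were, the calls were lost for erythroid (-0.54), heme synthesis (-0.35), hematopoietic progenitor (-0.15), mesenchyme (0.47), cardiac (0.80), parietal endoderm (0.89) and angiogenic ligand genes (0.32). Counting genes in their first list alone, which tests fewer genes, lost hematopoietic progenitors (-0.074) and angiogenic ligands (0.32). With 1 array left out, hematopoietic progenitors ranged from -0.27 without CKO replicate 2 to -0.12 without control replicate 2. Of lists not called, endothelial genes ranged from -0.067 to 0.053, arterial from -0.21 to 0.033 and venous from -0.032 to 0.10, each without control replicate 2 and 1 in that order, and hemangiogenic factors from -0.11 without CKO replicate 2 to -0.024 without CKO replicate 1. Immediate early genes went to 0.36 without CKO replicate 1, p53 targets ranged from 0.0093 without it to 0.063 without control replicate 2, and myeloid genes from -0.068 without CKO replicate 2 to -0.020 without control replicate 1. Amino acid stress genes went to -0.21 without control replicate 1 and 0.0089 without control replicate 2, megakaryocyte genes to 0.054 without control replicate 1, and visceral endoderm genes to 0.11 without control replicate 1, 0.019 without control replicate 2 and 0.026 without CKO replicate 2. Fry added calls for megakaryocyte (0.12), myeloid (-0.045), visceral endoderm (0.055), trophoblast (0.37), hypoxia (0.18), amino acid stress (-0.075) and immediate early genes (0.22). The hypoxia list also passed under cyclic loess (0.19), with no filter (0.11) and on the authors' values (0.089), and its limma adjusted p ranged over these from 0.016 to 0.0493. The cause was not tested.

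Of 1393 values of named genes under alternatives, 1327 kept their side, 66 lost the call and 0 reversed. The call of Etv2 was lost under 4 of 15 alternatives, as given beside it.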

Other observations

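All tests of explanations in this part were chosen after the results were seen. In the fixed list of unfolded protein and amino acid stress genes, 6 of 17 fell and 1 rose, or 7 and 2 adjusted over the list alone. The pseudokinase gene Trib3 fell by 1.59 ± 0.12, Ddit3 by 1.26 ± 0.14, the asparagine synthetase gene Asns by 0.97 ± 0.10 and Atf4, which encodes the factor that drives them, by 0.82 ± 0.10. Xbp1 at -0.41 and Phgdh at -0.48 also fell, Vldlr rose by 0.55, and the chaperone genes Hspa5 at 0.37 and Hsp90b1 at 0.19 did not pass the test. The list as a whole was not called (median -0.075, limma camera adjusted p = 0.214, and 0.483 with an estimated correlation). Of 11 immediate early genes, 5 rose and 2 fell, the same counts as adjusted over the list alone, with Klf4 at 1.21 and Jun at 0.95 against Junb at -0.77 and Fos at -0.56 (median 0.22, or 0.12 with no filter on dim probes, limma camera adjusted p = 0.242, and 0.483 with an estimated correlation).

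Hypoxia and glycolysis genes rose in 6 of 23 cases and fell in 1, or 7 and 1 adjusted over the list alone, with Ddit4 at 0.95, Ndrg1 at 0.75, Egln1 at 0.58 and Aldoc at 0.58 against Hk1 at -0.57. The hypoxia median was 0.18 (limma camera adjusted p = 0.0601, and 0.337 with an estimated correlation). The list was called with a replicate block, under cyclic loess, with no filter on dim probes, on the authors' values (median 0.089) and by fry. Of 21 cell cycle genes, Ccne1 fell by 0.70, E2f1 rose by 0.60 and Ccna2 by 0.53, and 18 did not pass, with 1 and 2 adjusted over the list alone (median 0.08, or 0.023 with no filter on dim probes, limma camera adjusted p = 0.652, and 0.762 with an estimated correlation). Of 13 p53 target genes, Phlda3 fell by 0.50, Bbc3 rose by 0.56 and Plk2 by 0.49, and 10 did not pass, with 1 and 2 adjusted over the list alone (median 0.01, limma camera adjusted p = 0.836, and 0.856 with an estimated correlation). Xist, which is expressed in females, rose by 1.05 ± 0.10 and the Y-linked gene Eif2s3y fell by 0.73 ± 0.11, both being above background on all 4 arrays, while Kdm5d at -0.33 and Uty at -0.34 did not pass. The labels give neither the sex of the embryos nor whether samples were pooled, so a difference in sex make-up between the groups is not excluded. Adjusted over those 4 sex-linked genes alone, 2 fell and 1 rose. The sex-linked median of -0.34 (-0.12 without background correction and -0.061 on the authors' values) had a limma camera adjusted p of 0.443, and 0.694 with an estimated correlation. The list median and the camera test cannot decide on sex make-up, since a difference in it moves Xist and the Y-linked genes in opposite directions. The estimates of all 4 genes went the way of more female tissue on the CKO-labelled arrays, although 2 did not pass. On chromosome X, 72 of 358 tested genes were higher and 27 lower, against 1453 and 1114 of 10227 on the autosomes.

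The lower erythroid genes could come from dilution of yolk sac RNA by extra tissue, from fewer erythroid cells or from less expression in each. Dilution by tissue that makes none of the visceral endoderm genes would lower those genes alike. They replaced the endothelial list in this test, since carried-over tissue can hold endothelium. Of the visceral endoderm genes, 12 had a mean log2 level between 6 and 12. Foxa1, Gata6 and Ihh, which rose, are among the 12, and Apoe, which fell, is not. The median of the 12 lay 0.806 above that of the erythroid genes in that range. The gap exceeded the SD of 0.496 among the 12, and the lowest of them stood at -0.15. These values argue against such dilution as the whole cause. Tissue that makes some of these genes could hold them up, so dilution by it stays open. The cardiac list, for one, shares 1 tested gene with the visceral endoderm list. A smaller share of erythroid cells, with each cell unchanged, should lower erythroid genes by about the same amount. The SD of 0.367 among the 20 erythroid genes in that range exceeded their mean standard error of 0.105, yet other cell types share some of these genes, so share and expression cannot be told apart. The flat globin values do not speak against fewer cells, since these probes read at 85.5% or more of the brightest probe on their array, where a bead array may no longer follow the amount of RNA.

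For the higher parietal endoderm, Prl2c and cardiac genes, carry-over of neighbouring tissue is a candidate explanation, and a change within the yolk sac was not tested. For parietal yolk sac with its giant cells, 2 of 3 tested giant cell genes outside the Prl2c family rose (Hand1 at 0.49 and Mmp9 at 0.54, with Prl3d3 at -0.09), too few to decide. The parietal endoderm genes are also made by other cells. All 13 were above background on the control arrays, which does not show which cells made them. For placental trophoblast or decidua, 3 of 7 genes other than Prl2c2 rose and 2 fell, which leaves it open. Of the 20 genes of that list on the array only 8 passed the detection filter. Tpbpa, Tpbpb, Ctsj, Ctsq and Psg21 were among those that did not. Hand1 counts among the higher genes here and among the giant cell genes, and it is also on the mesenchyme list. For embryo body tissue, 0 of 31 neural, ectoderm and paraxial mesoderm genes were above background on both CKO-labelled arrays and not on both control arrays. The 1 gene of the 31 detected on both arrays of either group was Nes. It rose by 0.73 ± 0.12 by its brighter probe and stood at 0.15 by the other. By detection there was no sign of neural, ectoderm or paraxial mesoderm tissue, but a small amount could lie below background. Heart tissue alone would bring none of these genes. Embryo body or heart tissue therefore stays open.

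Large changes were counted near Etv2 and near Kdr, although the labels do not say where the Cre sits. Within 50 tested genes to each side of Etv2, 4 of 100 genes differed at least 2-fold, Hamp, Fxyd3, Psmd8 and Klk6, against 2.003% elsewhere (Fisher's exact test, 2-sided p = 0.144). Around Kdr there were also 4, Kit, Igfbp7, Ugt2b36 and Slc34a2, and no tested gene stood between Kdr and Kit. As many were found in 15.003% of 8585 windows along the genome for Etv2 and in 15.003% for Kdr. By this count a segment from another strain or an effect of a Cre at Kdr on its neighbours may exist but cannot be told apart from chance. The count takes no account of size. Psmd8, at -2.77, was the largest named decrease, and Klk6 and Fxyd3 were among the 12 largest named increases. Whether changes of that size gather near Etv2 was not tested.

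A weaker response of endothelium to blood flow is a hypothesis for the lower Gja4, Gja5 and Klf2. Of 6 other tested flow-induced genes, 1 fell (Tmem100, at -1.63), 1 rose (Klf4, at 1.21) and 4 did not pass, and 5 of the 6 estimates were below 0. An earlier bound would have counted 1 of 6 against the hypothesis. It was replaced after the count was seen, because a gene short of the threshold is not shown to be unchanged, and the hypothesis stays open.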
